A study of Mus musculus with 2 samples.

How the data were processed

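H3K4me1 was measured by ChIP-seq in newborn mouse intestine in 2 biological replicates of 1 group. The deposited files are 4 peak lists in narrowPeak format on the mm10 assembly: 1 for each replicate, 1 made on both replicates together (the pooled list) and 1 of replicated peaks. Each replicate list derives from the alignments of that replicate. The pooled list derives from 2 alignment files, and the replicated list from the other 3 lists. Per the deposited descriptions, the list of replicate 1 and the pooled list each also used 2 other source files, and that of replicate 2 used 1. The enrichment in the deposited lists is a ratio (fold) over the peak caller's background, given by the authors for each peak without its exact scaling. The deposited lists also hold the -log10 p and -log10 q that the authors' peak caller gave each peak. The peak caller, its version, its threshold and the rule for replication are not given in the sources used here. Every peak of the replicated list was found in the pooled list and carries the pooled values. The labels name a possible control experiment, whose data were not analysed.

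No list holds read counts, so the sequencing depth is unknown, and the number of peaks and of covered bases does not stand for it. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only. Peaks on chromosomes 1 to 19, X and Y were used, which left out 2 peaks of replicate 2 on other scaffolds. Gene positions came from GENCODE release M21 and base composition from the GRCm38 genome, the same assembly as mm10. All 21911 protein-coding genes were used, each with 1 annotated 5′ end. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and samtools 1.23.1.

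Replicate overlap was the share of the peaks of 1 replicate that shared at least 1 bp with a peak of the other. It was compared with 200 circular shifts of the peaks along each chromosome from 3 Mb on, which keep widths and spacing; the smallest two-sided p they can give is 0.00995. Enrichment was compared across replicated peaks, using the highest peak of each replicate inside each replicated peak. Positions were taken from peak midpoints: promoter (within 1000 bp of a protein-coding 5′ end), then exon, intron and intergenic, each against the same kind of shift. The profile at 5′ ends used genes with no other protein-coding 5′ end within 5 kb. Coverage within 250 bp of the 5′ end was set against coverage 1000 to 2000 bp away on either side, by a two-sided permutation test of 100000 sign flips across genes. Domains were made by joining replicated peaks no more than 3 kb apart, with at least 2 peaks each.

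For 19 gene lists, the median over members of the bases covered by replicated peaks within 25 kb of the 5′ end was compared with 10000 random lists matched on gene length deciles. The two-sided permutation p was adjusted by the Benjamini-Hochberg method over the 19 lists, with a threshold of 0.05. The lists were intestinal epithelial transcription factors, enterocyte genes, secretory and enteroendocrine genes, stem cell and Wnt target genes, smooth muscle genes, mesenchyme and fibroblast genes, enteric neuron and glia genes, endothelial genes, blood and immune genes, hedgehog, BMP and Notch pathway genes, pancreas genes, liver genes, stomach genes, brain genes, heart and skeletal muscle genes, epidermis genes, housekeeping genes, Hox genes and olfactory receptor genes. For the difference between replicates, both lists were reduced to 60646 peaks with the highest -log10 p. The median over members of log2((replicate 1 bases + 500)/(replicate 2 bases + 500)) was then tested in the same way. Random lists describe these libraries and are not a test across animals; neighbouring genes share peaks, so p values of lists with clustered members (Hox and olfactory receptor genes) are too small. Both list tests were tested on simulated lists of 20 genes. The coverage test passed an unadjusted 0.05 in 2.5% of 200 lists with no bases added, in 65.5% with 500 bases added per gene and in 100% with 1000. The difference test did so in 3% of lists with no shift, and in 98.5% with a shift of 0.5 on the log2 scale. That shift was upward and was added to every member, also to genes without bases in either list, whose real ratio is 0. Medians of random lists seldom exceed 0, so nearly any upward shift passes. The 98.5% thus does not tell how often real differences would be found, or found after adjustment.

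Genes named in the text follow a rule. They are, for 18 lists (all but the olfactory receptors), the 3 members with the most covered bases and the member with the fewest. To these were added the 10 longest domains, the 5 replicated peaks with the highest enrichment, and the 5 genes with the largest replicate difference in each direction among those with at least 5000 covered bases in the higher replicate. A fixed set of markers was always included: Cdx2, Hnf4a, Vil1, Fabp2, Lct, Sis, Lgr5, Muc2, Myh11, Acta2, Foxf1, Phox2b, Ret, Sox10, Pecam1, Ptprc, Ptf1a, Alb, Sox2, Olig2, Myod1 and Gapdh. The lists, this rule, the tests and most alternatives were chosen before the data were examined. Alternatives covered the overlap rule, stricter -log10 q limits, equal list lengths, window and flank sizes, the set of 5′ ends, the matching of random lists, the value compared, the joining distance and leaving out each replicate. Sequence motifs and promoter CpG content were examined only for the closing section. With 1 group, no comparison of conditions was possible.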

Results

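The series measured monomethylation of histone H3 at lysine 4 (H3K4me1), a chromatin mark of enhancers and of the flanks of active promoters, by ChIP-seq (chromatin immunoprecipitation followed by sequencing). The tissue was whole intestine from healthy newborn mice (postnatal day 0). There was 1 group of 2 biological replicates, each a pool of male and female mice: replicate 1 pooled 15 mice, and the labels give no number for replicate 2. No other age, tissue or treatment was included, so the comparisons are between the replicates, and between places in the genome within them. The list of replicate 1 held 98896 peaks with a median width of 194 bp, covering 22.6 Mb. That of replicate 2 held 60648 peaks with a median width of 278 bp, covering 19.8 Mb. The pooled list held 78770 peaks over 21.6 Mb, and the replicated list 31955 peaks over 11.4 Mb, or 0.420% of the genome. Median enrichment was 3.09 in replicate 1, 3.16 in replicate 2 and 3.37 in the replicated list. Sequencing depth is unknown.

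Most of the 5 replicated peaks with the highest enrichment lay in introns, as did 56.2% of all replicated peaks. The replicated peak with the highest enrichment, 6.73, was in an intron of Smad3, which encodes a transducer of TGF-beta signals (mm10 chromosome 9, 63714960 to 63716459); it reached 5.54 in replicate 1 and 4.51 in replicate 2. An intron of Elmsan1 held the next one (chromosome 12, 84176736 to 84178510), at 6.54, with Pnma1 as the nearest 5′ end. Peaks at 6.35 lay in introns of Vps37c, whose product acts in endosomal sorting (chromosome 19, 10698843 to 10700739), and of Plekha7, which encodes an adherens junction protein (chromosome 7, 116287382 to 116288202). The remaining one of the 5 was intergenic, with Chd2, a chromatin remodeller gene, as the nearest 5′ end (chromosome 7, 73578135 to 73578548; enrichment 6.32).

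The broadest H3K4me1 domain covered part of Actn4, which encodes a non-muscle actinin. It was 37.6 kb long and held 25 replicated peaks (chromosome 7, 28918597 to 28956168). Domains in Susd6 (27.5 kb, chromosome 12), in the kinase gene Mapkapk2 (24.2 kb, chromosome 1) and between genes, nearest to Zfp36l2 (23.2 kb, chromosome 17) followed. Nek6 held 21.7 kb and Zmynd8 20.7 kb, both on chromosome 2, and Elmsan1 held 20.03 kb on chromosome 12. Further domains lay across Dgkz and Gm9821 (19.8 kb), in Rxra, which encodes a retinoid X receptor (19.6 kb), and in Bcar1 (19.6 kb). In all, 6301 domains held 17835 replicated peaks (55.8%), their median length was 2.09 kb, and 114 were at least 10 kb long. With replicated peaks limited to a -log10 q of at least 5, 76 domains were left, and with those that overlapped both replicate lists, 3882.

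The replicates shared far more peaks than shifted positions did, though most peaks of each list had no counterpart in the other. All 5 of the strongest replicated peaks, at Smad3, Elmsan1, Vps37c, Plekha7 and near Chd2, had an overlapping peak in each replicate. They were picked from the replicated list, where 67.8% of peaks overlapped both replicate lists, so they do not test the sharing. Of the peaks of replicate 1, 25.4% (25091 of 98896; 95% interval 25.1 to 25.6) overlapped a peak of replicate 2. Of those of replicate 2, 38.5% (23357 of 60646; 38.1 to 38.9) overlapped a peak of replicate 1. Shifted peaks overlapped in 1.41% (SD 0.0763) and 2.23% (SD 0.108), so the measured shares were 18.0 and 17.3 times as high (permutation p = 0.00995 for each, the smallest that 200 shifts allow). Overlap was 45.5% in the top decile of replicate 1 by -log10 p against 17.5% in the lowest decile, and 59.8% against 31.4% in replicate 2. Most peaks of both lists were weak, with -log10 p reaching down to 2.03 in replicate 1 and 2.07 in replicate 2. A -log10 q of at least 2 was reached by 11.3% of peaks in replicate 1 (11197) and 31.4% in replicate 2 (19057). Limited to such peaks in both lists, the overlapping share was 22.8% for replicate 1 and 13.3% for replicate 2. As a share of all bases covered in either list, overlap was 12.0%.

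**Figure D1:**
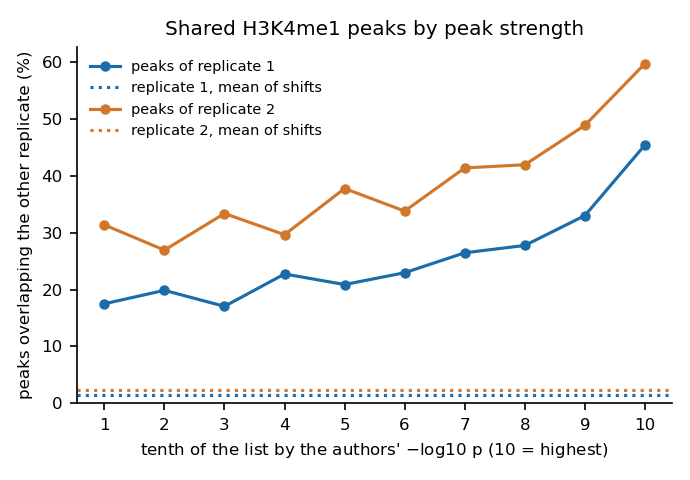
Percent of peaks that overlap a peak of the other replicate (vertical axis) by decile of the list ranked on the authors' -log10 p (horizontal axis, 10 = highest), with 1 line per replicate and dotted lines for the mean of 200 circular shifts. The top deciles lie at 45.5% and 59.8%, and every decile lies far above the shifted means of 1.41% and 2.23%.

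Peak heights were compared only where both replicates had a peak. Across the 21661 replicated peaks that overlapped both lists, the enrichment in replicate 1 and that in replicate 2 had a Spearman's rho of 0.105 (95% interval 0.0917 to 0.118) and a Pearson's r on log2 values of 0.111. These are correlations across peaks, which are not independent replicates, and weak peaks are missing because each had to be called in both lists, which narrows the range of heights and can lower a correlation. Enrichment was also coarsely stepped: the 10 commonest values held 61.9% of all peaks of replicate 1 and 52.7% of those of replicate 2. The SD of the log2 ratio between replicates was 0.36. The strongest intronic peak near the 5′ end of Smad7 reached 4.79 in replicate 1 and 4.77 in replicate 2, and that of Lrig1 4.22 and 2.57.

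The pooled peaks that passed the authors' replication step were the higher ones. They made up 40.6% of pooled peaks (31955 of 78770; 95% interval 40.2 to 40.9), with 90.4% in the top decile of enrichment, and 14.4% in the lowest. Of the replicated peaks, 67.8% (21661) overlapped a peak of each replicate list by at least 1 bp, and 32.2% (10294) lacked one or both. Genes whose strongest peak had a counterpart in 1 replicate only included Acta2, Lgr5, Tcf7l2, Insm1 and Sct. Among pooled peaks with a -log10 q of at least 2, 66.8% were replicated; requiring peaks of both replicates over 50% of the pooled peak gave 21.4%.

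Chromosome X carried almost no H3K4me1 peaks. The replicated list held 24 there, or 0.140 per Mb, against 13.0 per Mb on the autosomes, a 92.4-fold difference. The autosomes ranged from 8.83 per Mb on chromosome 14 to 22.0 on chromosome 11. Replicate 1 had 440 peaks on X (2.57 per Mb against 40.0 on the autosomes) and replicate 2 had 130 (0.760 against 24.6), so the density was lower on X in 2 of 2 replicates. Of 948 protein-coding genes on X, 17 (1.79%, 95% interval 1.05 to 2.86) had a replicated peak within 25 kb, against 55.0% on the autosomes. Ace2, an enterocyte gene on X, had 0 bases of replicated peaks, with 200 bases in replicate 1 and 0 in replicate 2. No list had a peak on chromosome Y.

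**Figure D2:**
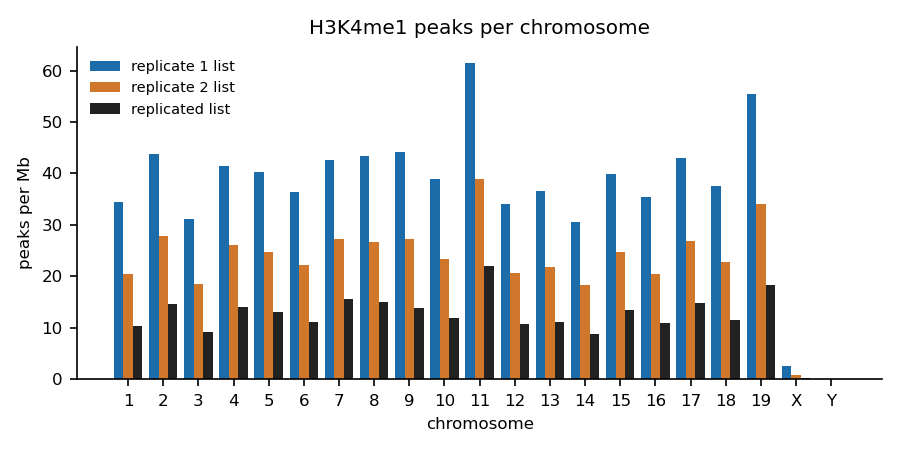
H3K4me1 peaks per Mb (vertical axis) on each chromosome (horizontal axis), with bars for the lists of replicate 1, replicate 2 and the replicated peaks. Bars for X stand at 2.57, 0.760 and 0.140 per Mb, below those of every autosome, and Y has 0.

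Most H3K4me1 peaks lay away from gene starts, within introns. Introns held 56.2% of replicated peaks (17966; 37.4% after shifting) and intergenic sequence 26.7% (8535; 57.3% after shifting). Examples of intronic peaks are those of Cdh17 on chromosome 4 (11769769 to 11770086) and of Ret on chromosome 6 (118179894 to 118180423). Promoters, within 1000 bp of a protein-coding 5′ end, held 11.2% (3584; 95% interval 10.9 to 11.6) against 1.71% after shifting, a 6.57-fold difference (permutation p = 0.00995, the smallest that the shifts allow). In the replicate lists the promoter share was 9.15% ± 1.48 (SD, n = 2). Promoter examples are peaks at Insm1, Notum, Sct and Gapdh, the last at -904 bp from the 5′ end. Exons held 5.85% (3.60% after shifting). The median distance to a 5′ end was 16.3 kb, against 68.7 kb after shifting, and 59.2% of peaks lay beyond 10 kb. A promoter of 2000 bp either side raised the share to 19.9%, one of 500 bp lowered it to 4.57%, and counting every transcript start gave 19.6%; each exceeded its shifted value.

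Around 5′ ends, the replicated peaks lay on both sides of the start with a gap between them. Across 17683 genes with no close neighbour, coverage reached 3.38% at 250 to 500 bp upstream and 4.16% at 1000 to 1250 bp into the gene, and was 1.70% in the first 250 bp of the gene. Within 250 bp of the 5′ end it was 1.82%, against 2.20% at 1000 to 2000 bp away, a difference of 0.384 percentage points (SE 0.0850; permutation p = 1e-05, the smallest that the sign flips allow). Flanks were more covered than the start at 2400 genes and less at 879, a count that favours the flanks because they span more bases. Genes are not independent replicates, so the SE and the permutation p describe these libraries only. The gap was in 1 of 2 replicates with these flanks: replicate 1 had 2.96% against 3.61%, while replicate 2 had 3.92% against 3.33%, a difference of -0.590. By the sign flips, both replicates had a permutation p of 1e-05, in opposite directions. Replicate 2 still had more genes with the flank higher (3432 against 1654), so such gene counts do not show a gap. Against flanks of 500 to 1500 bp, the flank was higher in replicate 2 as well, by 0.480, and in the replicated list by 1.04; with a -log10 q of at least 5, the difference was 0.0372 (permutation p = 0.0534).

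**Figure D3:**
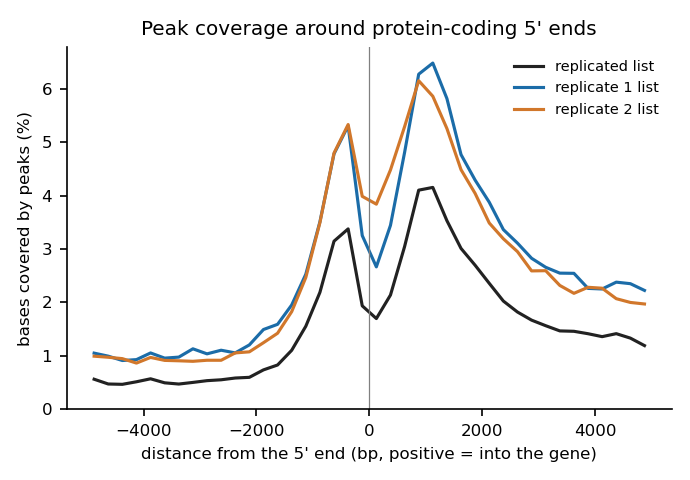
Percent of bases covered by peaks (vertical axis) by distance from the 5′ end in bp (horizontal axis, positive into the gene) over 17683 protein-coding genes, with a line each for the replicated list and both replicate lists. The replicated line peaks at 3.38% upstream and 4.16% downstream, with 1.70% in the first 250 bp between them.

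The list of genes of the hedgehog, BMP and Notch pathways, which pattern the gut tube and its epithelium, carried more H3K4me1 than random lists. The pathways were not tested apart, and Gli1 (780 bases) and Bmp4 (0) were counted in the mesenchyme list instead. Smad7, an inhibitor of TGF-beta and BMP signalling, had 7335 bases of replicated peaks within 25 kb of its 5′ end, in 23 peaks (chromosome 18, gene at 75367529 to 75395935); the replicates had 8812 ± 525 bases (SD, n = 2). The BMP target genes Id1 and Id3, encoding inhibitors of helix-loop-helix proteins, had 3386 bases (chromosome 2; 3860 ± 136 in the replicates, SD, n = 2) and 3252 bases (chromosome 4; 3791 ± 342, SD, n = 2). In contrast, Bmp2 had 0 bases of replicated peaks, with 1008 in the list of replicate 1 and 0 in that of replicate 2. Of the 21 members, 16 had a replicated peak, and the median was 1239 bases against 202 for random lists (95% range 0 to 609; permutation p = 0.0008, adjusted p = 0.0152). This was 1 of 19 lists past the threshold, with 2 at an unadjusted 0.05, and the median was higher than random in 2 of 2 replicates (2176 and 2658 bases). Counted as peaks rather than bases, the list had a median of 3 (adjusted permutation p = 0.0950). With peaks at a -log10 q of at least 5, where the medians of all 19 lists were 0, its mean of 160 bases compared with 23.2 for random lists (permutation p = 0.0280, adjusted p = 0.266).

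None of the 4 epithelial lists passed the threshold. Of all protein-coding genes, 52.3% had a replicated peak within 25 kb. Among intestinal transcription factors, Ehf, an epithelial ETS factor, had 2730 bases (5139 ± 120 in the replicates, SD, n = 2), Foxa3 1951 and Tcf7l2, a Wnt effector, 1766. The intestinal regulators Hnf4a and Cdx2 had 344 and 312 bases, and Atoh1, needed for secretory cells, had 0. The lists of replicates 1 and 2 held more: 1708 and 1736 bases at Hnf4a, 1533 and 448 at Cdx2, and 491 and 1360 at Atoh1. The list had a peak at 16 of 22 members, with a median of 463 bases (percentile 92.5 of random lists, adjusted permutation p = 0.597). With the list of replicate 2 alone, its median of 1306 passed the threshold (adjusted permutation p = 0.0405); with that of replicate 1 alone, 1165 did not (adjusted p = 0.163). For enterocyte genes, 15 of 25 had a peak and the median was 419 (adjusted permutation p = 0.597). Cdh17, encoding an intestinal cadherin, had 2994 bases, the triglyceride synthesis gene Dgat1 2078, the microvillus gene Vil1 1297 and the fatty acid binding protein gene Fabp2 1134. The disaccharidase genes Lct and Sis had 0.

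Stem cell and Wnt target genes had a peak at 16 of 19 members, with a median of 404 bases (adjusted permutation p = 0.597). Lrig1, a growth factor receptor regulator expressed in intestinal stem cells, had 6620 bases in 17 peaks (chromosome 6, gene at 94604529 to 94700158; 7892 ± 727 in the replicates, SD, n = 2). Ephb3, a crypt receptor gene, had 2673 and Notum, a secreted Wnt inhibitor gene, 2264, while Lgr5 had 179 and Cd44 had 0. In the lists of replicates 1 and 2, Lgr5 had 315 and 1142 bases and Cd44 had 1270 and 1416, so a 0 in the replicated list does not mean that no replicate had a peak. Secretory and enteroendocrine genes had a peak at 12 of 20 members (median 264, adjusted permutation p = 1): Sct, the secretin gene, had 1726 bases, Agr2 1694 and Insm1, an endocrine factor gene, 1419. Muc2, the goblet cell mucin gene, and Chgb had 0.

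None of the muscle, mesenchyme, nerve, vessel and blood lists passed the threshold (each an adjusted permutation p of 1). Smooth muscle genes had a median of 250 bases (12 of 18 members with a peak), led by the tropomyosin gene Tpm1 (2498), Smtn (1954) and Tpm2 (1133). The contractile genes Acta2 and Myh11 had 505 and 213, and Actg2 had 0. Mesenchyme and fibroblast genes had a median of 90.5 (10 of 20), with Gli1, a hedgehog effector, at 780, Hand1 at 549, Vim at 321, Foxf1, a gut mesenchyme factor, at 305 and Bmp4 at 0. Enteric neuron and glia genes had a median of 0 (6 of 20): Ret, the receptor that enteric neurons need, had 1425 bases, Tbx3 1301 and Phox2a 742, while Phox2b, Sox10 and Ascl1 had 0. Endothelial genes had a median of 181 (11 of 20), with the lymphatic gene Lyve1 at 2052, Sox18 at 1570, Nos3 at 1357, and Pecam1 and Cldn5 at 0. Blood and immune genes had a median of 194 (11 of 20), with Fcer1g at 1579, Klf1 at 1289, Vav1 at 804, and Ptprc and Cd3e at 0. A peak counts for every gene within 25 kb: the strongest one near Fcer1g lies in Tomm40l, and that near Klf1 in Dnase2a and Mast1. Random medians reach down to 0, so the median cannot show low coverage; by the mean over members, mesenchyme genes (171 bases; random range 219 to 1021; permutation p = 0.0174, adjusted p = 0.0826) and enteric neuron and glia genes (210; 214 to 991; p = 0.0468, adjusted p = 0.148) lay below random lists without passing the threshold.

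Nor did any list of another organ pass the threshold. Stomach genes had a median of 556 bases (8 of 12 with a peak; adjusted permutation p = 0.597), with Ghrl at 1445, Atp4a at 1158, Muc5ac at 756, Sox2 at 617 and Atp4b at 0. Brain genes had 490 (13 of 20; adjusted permutation p = 0.597), with Neurod2 at 1180, Bcl11b at 1094, Dlx1 at 993, and Olig2 and Camk2a at 0. The pancreas list had 253 (9 of 16; adjusted permutation p = 1), with Cel at 1557, Cela1 at 929, Nkx6-1 at 535, and Ptf1a and Amy2a5 at 0. Medians were 0 for liver genes (7 of 19), heart and skeletal muscle genes (5 of 19) and epidermis genes (4 of 18), each an adjusted permutation p of 1. Apoh (1594), Ttr (897) and Fgb (486) led the liver genes, with Alb and Ahsg at 0; by the mean over members, this list had 210 bases, below the random range of 233 to 1032 (permutation p = 0.0296, adjusted p = 0.112). Myl7 (2157), Tnnt2 (2037) and Tnni3 (1277) led the heart and skeletal muscle genes, with Myod1 and Acta1 at 0. Krt15 (2583), Tgm1 (1115) and Sbsn (567) led the epidermis genes, with Col17a1 at 0.

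Housekeeping genes had a peak at 18 of 20 members, and their median of 834 bases did not pass after adjustment (permutation p = 0.0098, adjusted p = 0.0931). Actb had 5031 bases, Rplp0 2574, Ywhaz 3129 and Gapdh 725, while Eef1a1 had 0. Matched on gene length quintiles and on the number of 5′ ends in the window, the list passed (adjusted permutation p = 0.0095). Hox genes, the positional regulators of the body axis, had a median of 202 (20 of 39; adjusted permutation p = 1). Hoxa4, Hoxa5 and Hoxa6 had the most, 1893 bases each from the same 5 peaks of the Hoxa cluster on chromosome 6. Hoxa1 had 0, with 1049 and 660 in the lists of replicates 1 and 2. The Hoxb and Hoxd clusters held 3 peaks each and Hoxc 0. Against random lists matched on GC content, the Hox median was lower than random (adjusted permutation p = 0.0152). Of 1134 olfactory receptor genes, 23 had a replicated peak (median 0, adjusted permutation p = 1). With either replicate list alone, or a 50 kb window, the list was lower than random (adjusted permutation p = 0.0019, 0.0019 and 0.0038). These settings matched on gene length only, and 948 of the 1134 genes lie in the lowest GC quintile. In its 2 deciles, 7.16% and 22.0% of all protein-coding genes had a replicated peak, so low GC content is not set apart here.

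**Figure D4:**
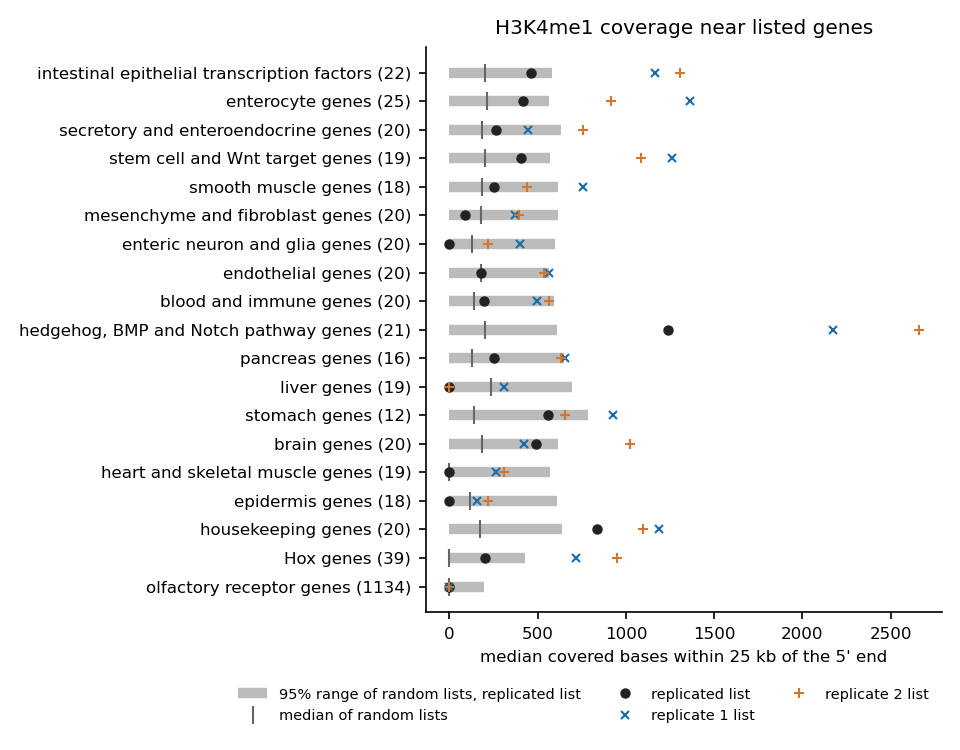
Median bases covered by peaks within 25 kb of the 5′ end (horizontal axis) for 19 gene lists (vertical axis, members in brackets), with points for the replicated list and crosses for each replicate list, and grey bars for the 95% range of 10000 random lists scored on the replicated list. The hedgehog, BMP and Notch list lies at 1239 bases, beyond its random range of 0 to 609; housekeeping genes lie at 834, which did not pass after adjustment.

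With both lists reduced to the same number of peaks, the Hox and liver lists lay outside the range of random lists in the difference between the replicates. Hox genes had more H3K4me1 in replicate 2, with a median log2 ratio of replicate 1 to replicate 2 of -0.60 (36 of 39 members; mean 567 against 1168 bases; permutation p = 0.0002, the smallest that random lists allow, adjusted p = 0.0038). With the lists as deposited, the Hox median was -0.17 (adjusted permutation p = 0.0076). The Hoxd cluster had 2655 bases in replicate 2, against 547 in the reduced list of replicate 1 and 1302 in its deposited list; the Hoxc cluster had 1443, against 220 and 699. The Hoxa cluster had 3350 bases in replicate 2, against 2130 in the reduced list of replicate 1 and 3426 in its deposited list; the Hoxb cluster had 3760, against 2008 and 3728. Liver genes had more in replicate 1, with a median log2 ratio of 0.16 (11 of 19 members, 3 the other way; mean 333 against 236 bases; adjusted permutation p = 0.0152). Of the liver genes named above, Ttr had a log2 ratio of 0.21 and Alb 0.70, while Apoh had -0.29. Alb had only 310 bases in the deposited list of replicate 1, 0 in that of replicate 2 and 0 in the replicated list. Its ratio thus rests on fewer bases than were added to both replicates before the log2 ratio. Both means of the liver list were below that added number too. Matched on GC content, neither list passed (adjusted permutation p = 0.146 for Hox and 0.137 for liver genes). By enrichment at shared peaks, the Hox median was 0.16, the other way (adjusted permutation p = 0.0709; 17 of 39 members have such a peak), and that of liver genes was 0.071 (adjusted p = 0.723).

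None of the other 17 lists passed this test. Medians were -0.43 for stem cell and Wnt target genes, -0.44 for blood and immune genes, -0.42 for hedgehog, BMP and Notch genes, -0.37 for secretory genes, -0.32 each for epithelial transcription factors, stomach and housekeeping genes, -0.22 for mesenchyme, -0.15 each for endothelial and brain genes, -0.09 for enterocyte genes, -0.06 for smooth muscle and -0.02 for pancreas. Those of enteric neuron and glia, heart and skeletal muscle, epidermis and olfactory receptor genes were 0. Among these lists the smallest adjusted permutation p was 0.286, and 2 of 19 lists, Hox and liver genes, passed an unadjusted 0.05. With the lists as deposited, where replicate 1 has more peaks, enterocyte genes had a median of 0.45 (adjusted permutation p = 0.0380). By enrichment at shared peaks, the 7 of 20 mesenchyme genes with such a peak had a median of -0.54 (adjusted permutation p = 0.0076).

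With lists of equal length, which cover 14.9 Mb in replicate 1 and 19.8 Mb in replicate 2, 279 genes had at least 5000 covered bases in the higher replicate: 262 had more in replicate 2 and 17 in replicate 1. With the lists as deposited, which cover 22.6 Mb and 19.8 Mb, 355 genes reached this number: 213 had more in replicate 2 and 142 in replicate 1. In the reduced lists, the largest difference was at Dpp4, which encodes a brush border peptidase (chromosome 2, gene at 62330073 to 62412231). Replicate 2 had 5267 bases there and the reduced list of replicate 1 had 359 (log2 ratio -2.75). The deposited list of replicate 1 had 2398 bases there, which gives a log2 ratio of -0.99. Myh7b (-2.25, and -1.66 as deposited), Fkbp10 (-1.89 and -1.04), Gtf2ird1 (-1.60 and -0.93) and P3h4 (-1.52 and -0.82) followed in the same direction. As deposited, Myh7b and Fkbp10 exceeded Dpp4. At shared peaks, the log2 ratio of enrichment at Myh7b was 0.0046. Fkbp10 and P3h4 are neighbours on chromosome 11. In the other direction, Mbnl2, a splicing regulator gene, had 0.42 (0.65 as deposited) and Anxa2 0.41 (0.57). Socs3, a cytokine signalling inhibitor gene, had 0.76 (1.03), its neighbour Pgs1 0.47 (0.71) and Rassf3 0.43 (0.72), though by enrichment at shared peaks these were at -0.021, -0.045 and -0.10. With 1 library for each pool, these differences have no error and no test.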

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

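The tests chosen only after seeing the data were the mean over members, peaks overlapping both replicate lists, matching on promoter CpG content, the mean at a -log10 q of at least 5, GC matching of the replicate difference, and peaks set to 300 bp. Unknown depth limits every peak count. Where a value changed, the cause was not tested, except for GC matching and the 300 bp width. Replicate overlap stayed above its shifted value under all 5 alternatives for replicate 1 (12.0% of bases to 29.3% of peaks) and all 4 for replicate 2 (13.3% to 28.5%), the promoter share under all 8 (4.57% to 19.9%), and the rank correlation of enrichment lay between 0.0962 and 0.112.

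The difference between flank and start at 5′ ends was -0.590 without replicate 1 and 0.655 without replicate 2; at a -log10 q of at least 5 it was 0.0372. The replicated share was 21.4% with 50% overlap by both replicates and 66.8% at a -log10 q of at least 2. Domains numbered 76 at a -log10 q of at least 5 and 3882 with peaks overlapping both lists.

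The count of gene lists past the threshold was 2 with a 50 kb window (olfactory receptors lower), 2 matched on length quintiles and number of 5′ ends (housekeeping higher), 2 matched on GC (Hox lower at a median of 202, a reversal), 2 by the mean (olfactory receptors lower), and 0 by number of peaks. It was also 0 at a -log10 q of at least 5, where the medians of all 19 lists were 0, so that setting is no test. Leaving out 1 replicate gave 2 to 3. The hedgehog, BMP and Notch median was 3 peaks (adjusted permutation p = 0.0950) and its mean at a -log10 q of at least 5 was 160 (adjusted p = 0.266). Apart from the void setting, in which its median was 0, its adjusted p ranged from 0.0019 to 0.266.

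The count of lists differing between replicates was 1 with a 10 kb window (Hox genes), 1 by enrichment at shared peaks (mesenchyme genes), 0 matched on GC and 1 at 300 bp (Hox genes). Liver genes lost their call in all 5 alternatives: 0 (10 kb), 0.39 (lists as deposited, adjusted permutation p = 0.0608), 0.071 (enrichment), 0.16 (GC) and 0.35 (300 bp). Hox genes had -0.17 with the lists as deposited (adjusted permutation p = 0.0076) and -0.60 matched on GC (adjusted p = 0.146), and reversed to 0.16 by enrichment, and enterocyte genes reversed to 0.45 with the lists as deposited. By enrichment, Socs3 (-0.021), Pgs1 (-0.045), Rassf3 (-0.10) and Myh7b (0.0046) reversed; the other 36 of 40 values for single genes kept their direction. Covered bases at named genes moved in 314 of 612 cases, and lengths of named domains in 31 of 32.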

Other observations

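Except for GC matching of the hedgehog, BMP and Notch list, the tests here were chosen only after seeing the data. Promoters differed in where H3K4me1 lay according to their CpG content. In the decile of genes with the most CpG within 500 bp of the 5′ end, replicated peaks covered 0.934% of bases at the start and 5.10% of the flanks, a difference of 4.17 percentage points (SE 0.281; 1725 genes). In the fifth decile it was the other way, with 4.13% at the start and 1.69% in the flanks (difference -2.43, SE 0.358; 1753 genes). Both held in each replicate: 1.43% against 7.66% and 3.22% against 7.28% in the top decile, and 6.28% against 3.19% and 7.21% against 2.85% in the fifth decile, for replicates 1 and 2. In the eighth decile the flanks were higher in replicate 1 only, with 2.89% against 6.10% in replicate 1 and 5.99% against 5.38% in replicate 2, the latter a difference of -0.614 with an SE of 0.515. In the replicated list, the lowest CpG decile had 0.0448% at the start and 0.0447% in the flanks. Differences there were also small in the second decile (-0.138, SE 0.134) and the sixth (-0.261, SE 0.321).

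In distal replicated peaks (25610, over 2000 bp from a 5′ end), some motifs were more frequent than in flanking sequence, those of HNF4 and GATA among them. The HNF4 motif, bound by regulators of enterocyte genes, was 1.64 times as frequent as in flanking sequence (95% interval 1.48 to 1.82), above all 20 permuted motifs of the same bases (at most 1.12). GATA (1.22), FOXA (1.25), TEAD (1.19), AP-1 (1.15), E-box (1.35) and SRF (1.32), the last a regulator of smooth muscle genes, also lay above every permuted motif. Only a minority of distal peaks held any of these motifs: 2.57% for HNF4, 12.9% for GATA, 8.23% for FOXA and 0.668% for SRF. The share was 13.9% for TEAD, 10.4% for AP-1 and 30.5% for E-box. The hypothesis that motifs of intestinal epithelial factors are more frequent in distal peaks than in their flanks was tested on CDX, HNF4 and GATA: 3 of 3 exceeded every permuted motif. For CDX, however, the ratio itself was 0.952 (0.917 to 0.986), so that motif was less frequent than in the flanks and exceeded only its permutations (at most 0.882). Motifs of KLF and SP, ETS, SOX, TCF and LEF, CTCF and REST did not exceed theirs, and 2 of 16 were too rare to assess.

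Few peaks lay on chromosome X, 0.140 per Mb against 13.0 on the autosomes. Gene number and GC content do not account for this: 1.79% of X genes had a replicated peak, below the lowest of 10000 autosomal sets matched on GC (29.6%, mean 35.4%). A lower signal from fewer X copies in pools of both sexes, or from the control used, may contribute and cannot be told apart from other sources. With autosomal enrichment scaled by 0.75, 49.99% of autosomal pooled peaks were still above the lowest X enrichment (2.25), but the enrichment at which a peak is called is not known. No biological explanation was tested.

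More H3K4me1 lay near hedgehog, BMP and Notch genes than near random genes. GC content of the windows and CpG content of the promoters do not account for the whole of it: with matched random lists the median of 1239 compared with 419 (adjusted permutation p = 0.0152) and 398 (adjusted p = 0.0380). The call was lost when peaks were counted instead of bases (adjusted permutation p = 0.0950). No biological explanation was tested, since the design has no other tissue or age.

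With lists of equal length, Hox genes had more H3K4me1 in replicate 2, and GC content is a candidate explanation: covered bases in replicate 2 were 1.19 times those of replicate 1 in the lowest GC decile of genes and 1.48 times in the highest, and 28 of 39 Hox genes lie in the top GC quintile. Matching on GC left the Hox median at -0.60 but moved that of random lists from 0 to -0.32 (95% range -0.57 to -0.08), which ended the call (permutation p = 0.0154, adjusted p = 0.146); with peaks 300 bp wide the median was -0.46 (adjusted p = 0.0038), so the wider peaks of replicate 2 are not the whole cause. For liver genes, higher in replicate 1, neither explanation gives a ratio above 0. Wider peaks add to replicate 2, and every GC decile of genes had a mean log2 ratio below 0. Against random lists, however, a list with few GC-rich genes lies higher. Mean ratios fell from -0.0149 in the lowest GC decile to -0.418 in the highest. Of the 19 liver genes, 1 lies in the top GC quintile and 3 in the lowest. GC matching changes only the random lists, so the liver median of 0.16 could not move. The median of random lists was 0 before and after matching (95% range -0.49 to 0 and -0.46 to 0). The permutation p rose from 0.0016 to 0.0072 (adjusted p = 0.137), which ended the call. With random medians at 0, this does not decide whether GC content contributes. At 300 bp the liver median was 0.35 (random range -0.23 to 0), so it did not shrink. The call ended there too (adjusted permutation p = 0.0589). A different share of neighbouring tissue in the pools stays open and untested.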
